A study of Mus musculus with 6 samples.

How the data were processed

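The study measured polyadenylated RNA in tumour-associated macrophages, the macrophages that populate a tumour. The cells came from tumours grown by injecting MC38 cells, a mouse colon carcinoma line, under the skin of male C57BL/6J mice aged 6 to 8 weeks. Per the labels' protocols, tumours were taken at 3 weeks and macrophages were sorted by flow cytometry as cells positive for CD45, CD11b and F4/80 and negative for the neutrophil marker Ly6G. The mice were PtipWT, with an intact Ptip gene, or PtipcKO, a conditional knockout. PTIP is the protein of the gene listed as Paxip1, a component of the MLL3 and MLL4 histone methyltransferase complexes. The labels used here name neither the Cre driver nor the deleted exons. There were 6 libraries, 3 per genotype, and the series design text calls them biological replicates.

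RNA was extracted with Trizol, selected on oligo-dT beads, fragmented and reverse-transcribed with random primers, per the labels' protocols. The submitters' processing notes name CASAVA, HISAT2 2.1.0, featureCounts and DESeq2, and the mouse build GRCm38, as tools and build the authors used. Their settings, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited table held 12746 genes. For each library the deposited table gave the authors' regularized logarithm (rlog) on the log2 scale, a DESeq2 transform that scales read counts between libraries and pulls low counts of a gene towards its mean. Genes with few reads therefore end in a narrow band of low or negative values, and a difference between such values understates the fold change. The same deposited table gave the authors' own comparison of knockout with wild type as a log2 fold change, a p-value and an adjusted p-value, per the file headers. The knockout columns carried the letter P where the sample titles carry KO. They were assigned to the PtipcKO samples because the table's header names only a comparison of KO with WT, and the sign of the authors' deposited fold change was that of PtipcKO minus PtipWT in 82.7% of genes. The number of columns of per-sample values left unused was 0. Read counts were not used here, so the depth of each library is unknown, and no counting interval or detection floor in reads can be given. The lowest rlog value differed between libraries, from -1.95 in PtipcKO replicate 1 to -1.01 in PtipWT replicate 3.

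Differences between genotypes were tested with limma 3.58.1 in R 4.3.3, two-sided, on the deposited log2 values, with genotype as the only term and an intensity trend in the empirical Bayes step. Genes with a mean over all libraries above 2 were tested, which kept 10126 and left out 2620. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Differences are PtipcKO minus PtipWT. Standard errors are those of the moderated fit, and SDs are over the 3 libraries of a genotype.

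Gene lists of macrophage programmes, other cell types and RNA handling, 35 in all, were fixed together with the test, the filter and the naming rule before the data were examined. Lists with at least 5 tested members, 28 of the 35, were tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists. They were tested again with a correlation estimated from the data and with fry, whose p asks whether a list's genes move one way on balance. Too few members were tested for the T cell (1), NK cell (1), B cell (3), eosinophil and mast cell (1), endothelial (2) and tumour epithelial (1) markers, and 0 mitochondrially encoded transcripts were in the table. Named genes were Paxip1, the 12 largest changes per direction among called genes whose libraries do not overlap, and, where a direction had no call, the 6 smallest p-values. Up to 3 members with the smallest adjusted p were named for every called list and for the NF-kB, interferon, MHC class II, alternative activation and MLL3/MLL4-PTIP lists, and the 2 most abundant members for called lists of another cell type. Genes named outside this rule are said to be so.

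Coordinates, transcript lengths and GC content came from the GENCODE M21 annotation of GRCm38, in which 12533 of the 12746 gene symbols were found. Of 51 named genes, 19 overlap another annotated gene, and reads of overlapping genes may not be separable. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for this step.

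The fit was tested on simulated data for this comparison, with 10126 genes given their observed means. With each genotype's observed spread, 0 of 50 genes changed by 2 log2 units were called, 8 of 50 changed by 4 and 23 of 50 changed by 6, and 6 unchanged genes were also called. With the PtipWT spread set to that of PtipcKO, 26 of 50 genes changed by 2 units were called, 39 of 50 changed by 4 and 46 of 50 changed by 6. A list lowered by 1.5 log2 units was recovered by camera, with 1 other list called. The simulated noise was independent between genes, so this does not test camera on lists whose genes vary together.

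The alternatives were no filter, a filter at a mean above 5, no intensity trend, robust empirical Bayes, library weights, median centring, quantile normalization, a replicate block, each library left out in turn, a test against a minimum log2 difference of 0.5, a rule without p-values on separated libraries, and rank-based, fry and estimated-correlation list tests. Removal of a loess trend of the difference on abundance was added after the data were seen.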

Results

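Transcripts were measured by RNA sequencing in macrophages sorted from MC38 tumours of 3 PtipWT and 3 PtipcKO samples. The study's title places PTIP in the control of inflammatory responses, and the comparison of genotypes asks which macrophage transcripts differ when the gene is disrupted. Each library is described by its rlog values on the log2 scale, because the depth is unknown.

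The PtipWT libraries varied far more among themselves than the PtipcKO libraries. Across genes, which are not independent replicates, Pearson's r between libraries was 0.549 to 0.661 within PtipWT and 0.864 to 0.915 within PtipcKO. Between genotypes r ran from 0.608 to 0.803. Each PtipWT library correlated better with every PtipcKO library than with any other PtipWT library, so r did not group the PtipWT libraries together. The median over tested genes of the SD between replicates was 1.80 in PtipWT and 0.49 in PtipcKO. Many transcripts that were moderately abundant elsewhere lay near the bottom of the scale in PtipWT libraries. Of the genes averaging above 5 in the other 5 libraries, 35.1% lay 3 or more log2 units below that average in PtipWT replicate 3 (2009 of 5721). The share was 8.83% in replicate 1 and 4.46% in replicate 2 of PtipWT, and 0.16%, 0.46% and 0.23% in PtipcKO replicates 1, 2 and 3. The median value of the tested genes was 3.32 in PtipWT replicate 3 and 5.52 to 5.84 in the other 5 libraries. No gene had an identical value in any pair of libraries.

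**Figure D1:**
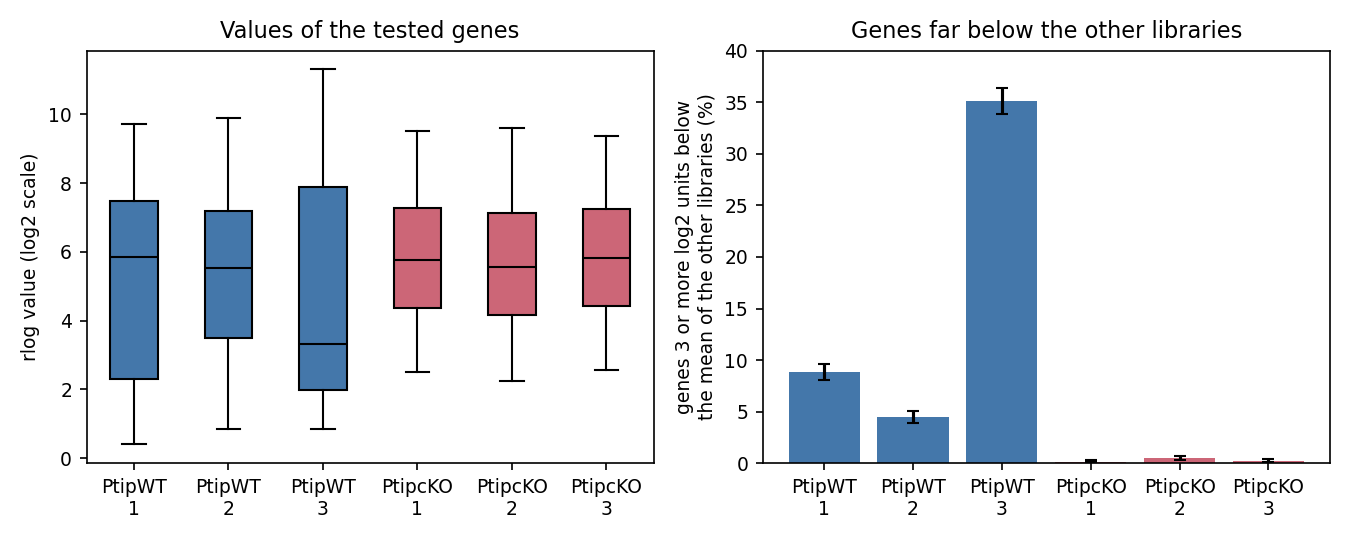
Left, rlog values (log2 scale) of the 10126 tested genes in each library, with boxes from the first to the last quartile, a line at the median and whiskers from percentile 5 to 95. Right, the percentage of genes averaging above 5 in the other 5 libraries that lay 3 or more log2 units below that average, with exact (Clopper-Pearson) 95% intervals over genes, which treat genes as independent. PtipWT replicate 3 reached 35.1%, and the PtipcKO libraries stayed at 0.46% or less.

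Paxip1, the gene that encodes PTIP, was lower in every PtipcKO library than in every PtipWT library. Its values were 6.08, 2.30 and 3.00 in PtipWT and -0.50, -0.25 and 1.997 in PtipcKO, with means of 3.79 ± 2.01 and 0.42 ± 1.37 (SD, n = 3 each). The difference of -3.37 log2 units (SE 1.08) did not pass the limma test (adjusted p = 0.208), and was -2.23 without PtipWT replicate 1. Paxip1 (ENSMUSG00000002221.11) lies on chromosome 5 from 27740080 to 27791691 on the minus strand of GRCm38 and overlaps no other annotated gene. The value covers the whole gene, so transcripts that lack only the deleted exons still count towards it. The authors' deposited table gave a log2 fold change of -5.37 and listed its p as 1, an entry that may mean that no test was made.

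Transcripts of 74 genes rose in PtipcKO macrophages, all from near the bottom of the scale in PtipWT, and 0 fell. St3gal6, a sialyltransferase gene, rose by 5.50 log2 units (SE 0.99), from 0.65 ± 0.32 to 6.15 ± 0.58 (SD, n = 3 each). Irgm1, an interferon-inducible GTPase that acts in defence against intracellular microbes, rose from 1.19 ± 0.57 to 6.63 ± 0.90. Slc7a7, a transporter of cationic amino acids, rose by 5.26 (SE 0.95), and Tapbpl, a peptide editor for MHC class I molecules, rose by 5.18 (SE 0.94). Trib3, a pseudokinase induced by endoplasmic reticulum stress, rose by 5.22 (SE 0.95). In PtipWT replicates 1, 2 and 3, St3gal6 was at 0.36, 0.60 and 1.00, Slc7a7 at 0.31, 0.54 and 0.93 and Trib3 at 0.28, 0.51 and 0.90. Irgm1 was at 0.6, 1.73 and 1.25. Such near-equal values of different genes lie in the narrow band of genes with few reads. Their small PtipWT SD need not show the spread between replicates.

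The other genes among the 12 largest rises were Rnf14, a ubiquitin ligase, Vps18, a subunit of endosomal tethering complexes, Sdccag8, a centrosomal protein, Rars2, the mitochondrial arginyl-tRNA synthetase, Cdc16, a subunit of the anaphase-promoting complex, Shisa4 and Mrpl1, a mitochondrial ribosomal protein. Their differences were between 4.93 and 5.37. Each of the 12 was higher in all 3 PtipcKO libraries than in any PtipWT library, with an adjusted p of 0.0493 in limma. St3gal6, Rnf14, Slc7a7, Sdccag8 and Tapbpl overlap another annotated gene. Over the 74 genes no PtipWT library exceeded 1.73, the PtipcKO means ran from 3.804 to 6.63, and the differences ran from 3.55 to 5.50. Of the 74, 2 genes, Irgm1 and Trib3, belonged to a programme list fixed in advance. All 35 lists together held 703 entries among the 12746 genes, so few members would be found in any 74 genes.

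The calls stood at the edge of the threshold, since 0.0493 was the smallest adjusted p of any gene. With no filter, no intensity trend or robust empirical Bayes, 0 genes were called. Library weights, median centring and quantile normalization also left 0. Without PtipWT replicate 3, the library with 35.1% of genes far below the others, 0 genes were called in either direction, and the same held without PtipWT replicate 1 for rises and without PtipcKO replicate 1 or 3, whereas 654 rose without PtipWT replicate 2. The median difference of the 74 genes was 4.38 without PtipWT replicate 3 and 4.23 with it. At an unadjusted p under 0.05, 977 genes were higher and 85 lower, against 485 and 486 after quantile normalization. The median difference over tested genes was 0.71, with 6682 genes above 0 and 3444 below. In 1366 genes every PtipcKO library was above every PtipWT library and in 378 every one was below, together 17.2% of genes. Interchangeable libraries would give 10%, but the spread was far larger in PtipWT, so no excess over chance can be read from this share. A separation can also be minute at low values. Lmo1, named outside the rule, was at 0.6452 in PtipWT replicate 1 and 0.6446 in PtipcKO replicate 2. The median difference was 1.28 for genes averaging 2 to 4, 1.00 for 4 to 6, 0.49 for 6 to 8, -0.60 for 8 to 10 and -0.67 above 10.

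**Figure D2:**
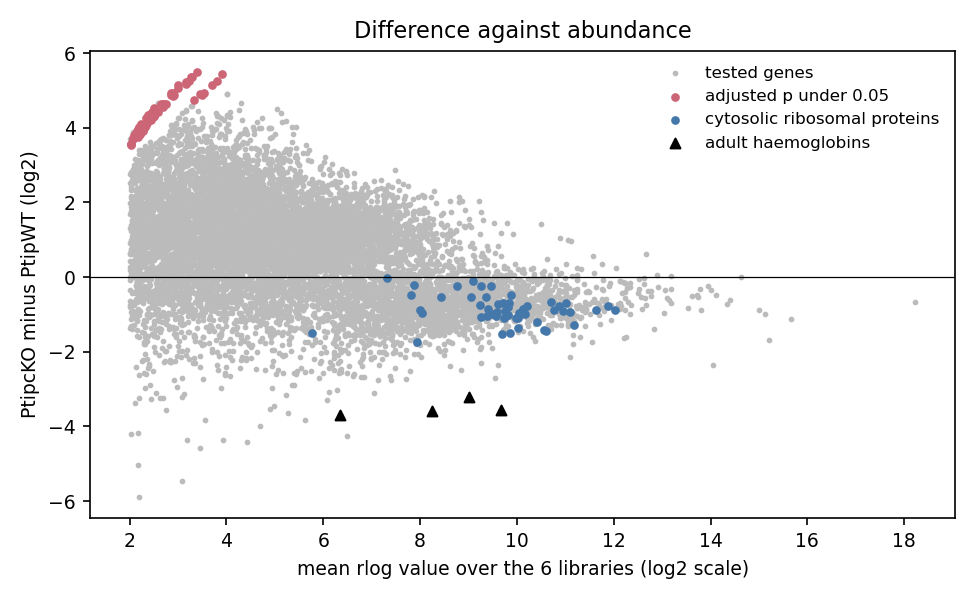
PtipcKO minus PtipWT difference (log2) of each tested gene against its mean rlog value over the 6 libraries (log2 scale). Red points are the 74 genes with an adjusted p under 0.05, blue points the 52 cytosolic ribosomal proteins and black triangles the 4 adult haemoglobins. The called genes all average between 2 and 4, while every ribosomal protein lies below 0.

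Among genes with lower values in PtipcKO, Lyz2, the lysozyme of macrophages and other myeloid cells, came closest to the threshold. It averaged 15.23 ± 0.58 in PtipWT and 12.87 ± 1.17 in PtipcKO (SD, n = 3 each), a difference of -2.36 (SE 0.50) with a limma adjusted p of 0.0505. Slpi, a secreted inhibitor of leukocyte proteases, averaged 8.62 ± 0.54 and 4.37 ± 0.80 (adjusted p = 0.107). Ccl6, a macrophage chemokine, was at 13.03 ± 0.09 and 11.41 ± 0.43, and Gm2a, the activator of ganglioside breakdown in lysosomes, at 13.07 ± 0.36 and 11.46 ± 0.23 (adjusted p = 0.130 for both). Their differences shrank from -1.62 and -1.61 to -0.86 and -0.87 after quantile normalization. The alpha-globins Hba-a1 and Hba-a2 differed by -3.55 (adjusted p = 0.116) and -3.58 (adjusted p = 0.138). None of the 6 genes passed, although in each all 3 PtipcKO values were below all 3 PtipWT values. Without PtipWT replicate 2, Lyz2 (adjusted p = 0.0453), Slpi (adjusted p = 0.0473) and Ccl6 (adjusted p = 0.0463) passed, and Lyz2 also passed without PtipcKO replicate 2 (adjusted p = 0.0308). Reads of Hba-a1 and Hba-a2, and of Lyz2 and its paralog Lyz1, cannot be assigned with certainty because the copies are nearly identical.

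**Figure D3:**
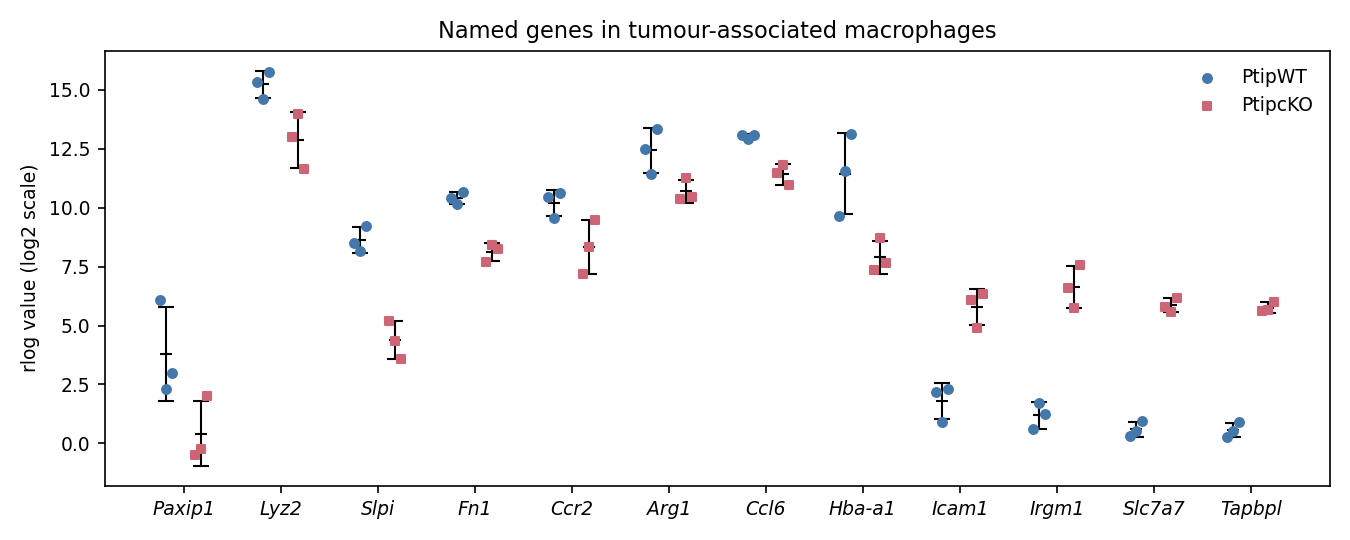
rlog values (log2 scale) of 12 genes in the 3 PtipWT libraries (blue circles) and the 3 PtipcKO libraries (red squares), with the group mean and SD in black. Irgm1, Slc7a7 and Tapbpl passed the test, and the other genes shown did not. In PtipWT the 3 genes that passed lie at or below 1.73.

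Cytosolic ribosomal protein transcripts were lower in PtipcKO across the whole list. All 52 members had a negative difference, with a mean of -0.87 ± 0.38 (SD over genes) against 0.70 for all other genes. Rpsa differed by -1.46, Rps4x by -1.51 and Rpl22 by -1.73, and 0 members passed over all genes or adjusted over the list alone. The list ranked below other genes in camera (adjusted p = 5.34e-16), a call that was lost with an estimated correlation (adjusted p = 0.480 with an estimated correlation). Its mean was highest in PtipWT replicates 3 (10.81) and 2 (10.38), the other 4 libraries lying at 9.07 to 9.55. After quantile normalization the list's distance from other genes shrank from -1.56 to -0.12 and the call was lost (adjusted p = 0.332). Ribosomal protein genes have many processed pseudogenes, so their read assignment is uncertain.

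Transcripts of oxidative phosphorylation, the mitochondrial respiratory chain, also ranked low, with 26 of 34 members negative and a mean of -0.22 ± 0.82 (camera adjusted p = 6.29e-04, or adjusted p = 0.480 with an estimated correlation). Among members, 0 passed over all genes and 0 adjusted over the list alone. Ndufb8, a subunit of complex I, differed by -1.09, while Sdhc and Sdha, subunits of succinate dehydrogenase, differed by 1.92 and 2.05, or 0.48 and 0.61 without PtipWT replicate 3. With 1 library left out, Ndufb8 ran from -1.75 to -0.74 and Sdha up to 3.51. The list was no longer called without PtipWT replicate 3 (adjusted p = 0.168) or among genes with a mean above 5 (adjusted p = 0.0585), and after quantile normalization it ranked above other genes (adjusted p = 0.0419).

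Of the marker lists of cells other than macrophages, those of red blood cells and platelets, neutrophils, and fibroblasts and pericytes ranked below other genes in camera with the preset correlation, with 0 members passing over all genes. All 6 tested erythroid and platelet markers were negative, with a mean of -2.53 ± 1.55 (camera adjusted p = 1.74e-07, or adjusted p = 0.457 with an estimated correlation). The haemoglobin gene Hbb-bs differed by -3.23. Adjusted over the list alone, 4 members passed. Pf4, a platelet chemokine that macrophages also express, was at 11.60 ± 0.69 in PtipWT and 10.65 ± 0.34 in PtipcKO, a difference of -0.96 that was -0.62 without PtipWT replicate 2. The list's means were 8.41, 10.31 and 10.14 in PtipWT and 6.79, 7.91 and 6.57 in PtipcKO, so every PtipcKO library was below every PtipWT library.

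Neutrophil markers averaged -2.05 ± 1.68, with 7 of 8 negative (camera adjusted p = 6.29e-04, or adjusted p = 0.457 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits, differed by -4.00 and -3.46, Trem1 by -2.59 and Mmp8, neutrophil collagenase, by -1.31, and 0 members passed either adjustment. Without PtipWT replicate 3, S100a8 differed by -2.54, Mmp8 by 0.51 and the list's distance from other genes went from -2.74 to -1.12. The list's mean was 8.72 in PtipWT replicate 3 and 2.46 to 5.03 in the other 5 libraries, with PtipWT replicate 1 (3.81) below PtipcKO replicate 1 (5.03), and the call was lost without that library (adjusted p = 0.244) and with library weights (adjusted p = 0.104). Fibroblast and pericyte markers averaged -0.995 ± 1.43, with 6 of 9 negative (camera adjusted p = 0.0027, or adjusted p = 0.457 with an estimated correlation). Dcn, a matrix proteoglycan, differed by -2.66, the collagen genes Col3a1 and Col1a1 by -2.44 and -2.67 and Sparc by -0.63, with 0 members passing either adjustment. Col3a1 differed by -1.52 without PtipWT replicate 3, and Sparc ran from -1.13 to -0.08 with 1 library left out. In the list's mean, PtipWT replicate 1 (5.10) lay below PtipcKO replicates 1 (5.46) and 2 (5.23). This list was not called without PtipWT replicate 2 (adjusted p = 0.208). Dendritic cell markers averaged 1.45 ± 1.38 over 6 members and were not called (adjusted p = 0.410).

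Monocyte genes, which mark cells newly arrived from blood, ranked low in PtipcKO with a mean of -0.32 ± 1.14 over 16 members, of which 9 were negative (camera adjusted p = 0.0055, or adjusted p = 0.457 with an estimated correlation). Fn1, fibronectin, was at 10.41 ± 0.26 in PtipWT and 8.11 ± 0.37 in PtipcKO, and Ccr2, the receptor that draws monocytes into tissue, at 10.20 ± 0.55 and 8.33 ± 1.16. S100a6 differed by -1.46. All 3 PtipcKO values were below all 3 PtipWT values for Fn1 and Ccr2, but 0 members passed over all genes or adjusted over the list alone. In the list's mean, PtipWT replicate 3 (4.96) lay below every PtipcKO library (5.75 to 6.06). The call was lost without PtipWT replicate 1 (adjusted p = 0.223) or 2 (adjusted p = 0.0753).

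Inflammatory mediators driven by NF-kB showed no common direction, with 15 members positive and 13 negative, a median of 0.11 and a mean of 0.002 ± 1.87. The list lay 0.69 below other genes without passing (camera adjusted p = 0.110), a distance that ran from -1.15 to -0.08 with 1 library left out and was smallest without PtipWT replicate 3, and 0 members passed over all genes or adjusted over the list alone. Icam1, an adhesion molecule, differed by 3.98 (adjusted p = 0.137) and Relb, an NF-kB subunit, by 3.30 (adjusted p = 0.188, or 0.0441 without PtipWT replicate 2). Cxcl2, a neutrophil chemokine, differed by -2.49 (adjusted p = 0.301), or -1.52 without PtipWT replicate 3. Interferon-stimulated genes averaged 1.32 ± 1.48, with 24 of 32 positive, and were not called as a list (camera adjusted p = 0.179), although after quantile normalization they were called higher, 0.87 above other genes (adjusted p = 0.0035). Irgm1 was the 1 member that rose, over all genes and adjusted over the list alone. Usp18, which restrains interferon signalling, was at 3.01 ± 1.38 in PtipWT and 6.35 ± 0.50 in PtipcKO, and Ifit2 at 2.47 ± 2.17 and 5.95 ± 0.36, and they passed only without PtipWT replicate 2 (adjusted p = 0.0479 and 0.0441).

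Genes of alternative activation averaged -0.03 ± 1.54, with 11 of 18 negative (camera adjusted p = 0.0598), and 0 passed over all genes or adjusted over the list alone. Arg1, arginase, which depletes arginine, was at 12.43 ± 0.97 in PtipWT and 10.69 ± 0.50 in PtipcKO with all libraries separated (adjusted p = 0.228, or 0.0449 without PtipWT replicate 2). The folate receptor gene Folr2 differed by 2.62 and the lectin gene Clec10a by 3.27, and they passed only without PtipWT replicate 2 (adjusted p = 0.0446 and 0.0441). The list was called lower without PtipWT replicate 3 (adjusted p = 0.0015) or PtipcKO replicate 3 (adjusted p = 0.0144) and with library weights (adjusted p = 0.0245), while without PtipWT replicate 1 its distance from other genes was -0.36 (adjusted p = 0.441). MHC class II genes, which present antigen to helper T cells, had a median difference of 0.44 and a mean of 0.12 ± 1.20 over 13 members but ranked below other genes, without passing (camera adjusted p = 0.0753). Cd74 and H2-Eb1 were lower in every PtipcKO library than in any PtipWT library, with differences of -0.96 and -1.45, and Cd40 differed by 2.46, or 3.71 without PtipWT replicate 1, with 0 members passing. This list was called lower without PtipWT replicate 3 (adjusted p = 0.0189) or PtipcKO replicate 3 (adjusted p = 0.0144), without PtipWT replicate 1 its distance from other genes shrank from -0.56 to -0.07 (adjusted p = 0.627), and after quantile normalization its sign turned (0.02 above other genes, adjusted p = 0.932).

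The list named for the MLL3/MLL4-PTIP complex, whose members need not all be its subunits, showed 10 positive and 7 negative. It was not called (camera adjusted p = 0.392), and 0 members passed. Besides Paxip1, the histone demethylase gene Kdm6a differed by 2.103 and Kdm6b by -1.09, or -0.62 without PtipWT replicate 2. After quantile normalization Kdm6a differed by 0.14 and Kdm6b by -0.30. Histone acetylation factors averaged 0.85 ± 1.10, with 25 of 31 positive (adjusted p = 0.579), against 0.69 for other genes.

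Among macrophage lists, tissue-macrophage identity genes averaged 0.11 (adjusted p = 0.0650), TREM2-type lipid-handling genes 0.21 (adjusted p = 0.110), phagocytosis and scavenger receptors 0.52 (adjusted p = 0.392), lysosomal genes 0.41 (adjusted p = 0.344) and chemokine and cytokine receptors 0.79 (adjusted p = 0.698). T cell suppression and checkpoint ligands averaged 0.63 (adjusted p = 0.548), angiogenesis and matrix genes 0.36 (adjusted p = 0.548) and MHC class I genes 0.79 (adjusted p = 0.924). Metabolic and stress lists were glycolysis at 0.09 (adjusted p = 0.0598), hypoxia at 0.38 (adjusted p = 0.377), cholesterol synthesis at 0.68 (adjusted p = 0.924), the unfolded protein response at 0.57 (adjusted p = 0.579), dissociation stress at 0.31 (adjusted p = 0.284), DNA damage at 0.88 (adjusted p = 0.764) and cell cycle at 1.21 (adjusted p = 0.135). None of these lists was called by camera, and in them 1 gene, Trib3, rose over all genes tested. Glycolysis was called lower without PtipWT replicate 2 (adjusted p = 0.0019), without PtipcKO replicate 1 (0.0179) or 3 (0.0184) and among genes with a mean above 5 (0.0305), and tissue-macrophage identity without PtipcKO replicate 3 (0.0192). TREM2-type and lysosomal genes were called lower without PtipWT replicate 2 (0.0205 for both). After quantile normalization the MHC class I, TREM2-type, lysosomal, unfolded protein response and cell cycle lists were called higher (camera adjusted p = 0.000116 to 0.0184). Adjusted over the list alone, 2 genes passed in the unfolded protein response list and 1 each in the angiogenesis, hypoxia and dissociation stress lists, all higher. Because all other genes averaged 0.69, lists with small positive means ranked below them. Medians were negative where means were positive for tissue-macrophage identity (-0.05), TREM2-type (-0.22), glycolysis (-0.37), lysosomal (-0.05) and dissociation stress genes (-0.05).

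The authors' deposited table listed 214 genes at an adjusted p under 0.05, 159 higher and 55 lower in PtipcKO, and 68 of the 159 were among the 74 called by limma. In that table Slpi (log2 fold change -5.43) and the haemoglobins Hba-a1 (-5.21), Hba-a2 (-5.35), Hbb-bs (-4.95) and Hbb-bt (-5.29) were among the lower genes, Hbb-bt being named here after its values were seen. Of its higher genes, 104 had all 3 PtipWT rlog values under 2. Of its 55 lower genes, 36 had 1 PtipWT library that exceeded both others by 3 or more log2 units. The authors' deposited table listed a p of exactly 1 for 1212 genes, among them Paxip1, S100a8, Cxcl2, Mmp8 and Cd40, and an adjusted p of 1 for 2941. Its adjusted p for the other 9805 genes equalled a Benjamini-Hochberg adjustment over those genes alone to within 1.51e-05, so a 1 may stand for a gene left out rather than a test result.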

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

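Removal of the abundance trend was chosen after the data were seen, and all other alternatives before. The 74 rises were the least stable result. The count was 0 with no filter, with a mean above 5 (which removes all 74 by construction), without an intensity trend, with robust empirical Bayes (smallest adjusted p 0.0519), with library weights, after median centring, after quantile normalization, after removal of the abundance trend and in the test against a minimum difference of 0.5. Leaving out 1 library gave 0 to 654 rises, 0 to 8 falls and 5 to 10 lists lower, with 0 lists higher. All 74 were shared with the 654 without PtipWT replicate 2, and 64 of the 69 without PtipcKO replicate 2. Genes with separated libraries and a difference of 1 or more numbered 1343 higher and 288 lower, with no p-value. Median centring and quantile normalization moved the median difference of all genes from 0.71 to -0.11 and 0.04, so directions under them are relative to that shift.

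The 6 lists lower numbered 0 with an estimated correlation and 0 in fry, and 6 in the rank-based test. Lists higher numbered 0, but 1 after median centring, 7 after quantile normalization and 6 after removal of the abundance trend. Reversed differences were those of Mmp8 with library weights (0.58) and without PtipWT replicate 3 (-2.64 to 0.51 over the left-out libraries), Sparc after quantile normalization (0.16), the MHC class II list after quantile normalization (0.021) and trend removal (0.064), and the oxidative phosphorylation list after quantile normalization (0.42) and trend removal (0.26). Apart from the filter, the cause was not tested. For the other named genes and lists, 578 and 142 refits kept direction and side of the threshold, 136 and 9 lost the call and 12 and 9 gained one. The 136 were all refits of the genes named as largest rises. Those genes kept the call only with the replicate block, without PtipWT replicate 2 and, for some of them, without PtipcKO replicate 2. The 578 were mostly uncalled genes that stayed uncalled.

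The difference of Paxip1 was negative under all alternatives run and -4.16 to -2.23 with 1 library left out. Its adjusted p ran from 0.0461 to 0.807, and at a mean above 5 it was not tested. Whether the replicate numbers pair the samples could not be settled. Deviations of same-numbered libraries correlated at 0.002, 0.136 and -0.041, and PtipWT replicate 1 correlated best with PtipcKO replicate 3 (0.138). With 3 libraries per genotype such weak values cannot exclude pairing. With the replicate block 86 genes rose, all 74 among them, and 12 fell. The falls included Paxip1 (-3.37, adjusted p = 0.0461), Lyz2 (adjusted p = 2.17e-08) and Hba-a1 (adjusted p = 0.0109). The NF-kB (adjusted p = 0.0385), alternative activation (adjusted p = 0.044) and glycolysis lists (adjusted p = 0.0385) were called lower. Same-numbered Lyz2 values fell unevenly, from 15.32 to 13.01, 14.61 to 13.97 and 15.76 to 11.63. The block leaves few residual degrees of freedom, so these gene p-values rest largely on the empirical Bayes step and not on like falls in each pair. The adjusted p of Lyz2 ran from 2.17e-08 to 0.837 over all alternatives. Depth is unknown, and the spread within PtipWT limited detection.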

Other observations

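The genes and tests chosen only after results were seen were the widest-gap genes, the lists after trend removal, PtipWT replicate 3 alone, red blood cell RNA and the Lyz2 insertion. Genes with a mean above 5 over all 6 libraries, 5277 in all, were searched for gaps of at least 1 log2 unit between the genotypes' nearest libraries. In 11 genes PtipcKO lay below, among them Slpi with a gap of 2.96, the chemokine Cxcl14 with 2.07, Fn1 with 1.74 and Krt14, a keratin of basal epidermis, with 1.21. Cxcl14 averaged 8.59 ± 0.92 in PtipWT and 5.49 ± 0.44 in PtipcKO, and Krt14 averaged 9.08 ± 1.13 and 6.36 ± 0.68 (SD, n = 3 each). In 42 genes PtipcKO lay above, led by Gm45828 (2.71), Cops4, a subunit of the COP9 signalosome (2.68), and Nckap1l, a subunit of the WAVE complex in blood cells (2.55). Cops4 averaged 3.44 ± 1.18 in PtipWT and 7.45 ± 0.29 in PtipcKO. The counts depend on the choice of genes, since an earlier search of the 2422 genes above 5 in every PtipWT library, a choice that favours lower values in PtipcKO, gave 12 below and 2 above. None of the genes named here passed over all genes in limma.

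After a loess trend of the difference on abundance was subtracted, 6 lists ranked higher in PtipcKO with the preset correlation. These were interferon-stimulated genes (adjusted p = 0.048), MHC class I (0.032), TREM2-type lipid handling (0.006), cell cycle (0.004), lysosome (0.008) and the unfolded protein response (0.012). None was called with an estimated correlation, with adjusted p of 0.296 to 0.568, and 0 genes were called, with 281 higher and 237 lower at an unadjusted p under 0.05. Without the subtraction none of the 6 lists was called higher with 1 library left out, and TREM2-type lipid handling and lysosome were called lower without PtipWT replicate 2 (0.0205 for both). After quantile normalization, which also removes differences between the libraries' distributions, all 6 were called higher (0.000116 to 0.0184), and cell cycle was after median centring (0.0438).

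The 74 rises may reflect transcripts lost from PtipWT libraries, or a response to loss of PTIP. In all 3 PtipWT libraries, 179 of 8805 genes lay 3 or more log2 units below the PtipcKO mean. Independent loss in each library would give 67.9, and the ratio was 2.64 (exact Poisson 95% interval 2.27 to 3.05, treating genes as independent). The 179 held all 74, which largely follows from how these were called. The expectation used each library's mean rate of loss among genes of like PtipcKO mean. Genes unequally prone to loss would also raise the ratio. The converse count, low in all 3 PtipcKO libraries, also exceeded its expectation (14 against 0.016). The excess thus argues only against independent loss at equal rates as the whole cause, and independent loss may account for part of the 74. Replicate 3 of PtipWT alone is not the source of the low values, which were at most 1.26 in replicate 1 and 1.73 in replicate 2, while the median difference without it, 1.035 times that with it, follows from how the genes were called and says nothing about loss in all 3. Loss that follows transcript length stays open and would make losses coincide, because the called genes had a median longest-transcript length of 2352 bp against 3541 bp in lists matched on PtipcKO mean (percentile 0.01, the smallest that 10000 lists can give), while their GC content, at percentile 87.3 of matched lists, lay within the range set for no effect. The real split called 74 genes and the highest of the other splits 0, so 1 of the 10 splits reached that count, and 10 splits are too few for a share under 0.05, while genotype is confounded with the spread among PtipWT libraries, so an effect of PTIP stays open and untested.

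For the 6 lower lists, a difference that follows abundance may account for much of the distance of the ribosomal proteins from other genes. Once the trend was removed, that distance shrank from -1.56 ± 0.38 to -0.25 ± 0.46 (SD over genes). This ended the camera call (adjusted p = 0.121). The list's median difference still lay at percentile 0.08 of randomly drawn lists matched on mean value. Those draws treat genes as independent, so abundance as the whole cause stays open there. With the preset correlation abundance is not the whole cause for the erythroid list, which kept -2.37 ± 1.54 of -3.22 (adjusted p = 4.78e-05). Nor is it for the other called lists, of which 3 of 4 were still called, oxidative phosphorylation being the exception. But with an estimated correlation none of these lists was called before or after (adjusted p = 0.296 to 0.357 after for the 4 lists still called with the preset correlation). In the test for RNA of red blood cells in the PtipWT libraries, 4 of 4 adult haemoglobins were separated. Hba-a1 was at 11.44 ± 1.73 in PtipWT and 7.89 ± 0.71 in PtipcKO. The test was chosen after results were seen and restates the fall that prompted it, so RNA of red blood cells stays open. A sort for CD45, CD11b and F4/80 selects against such cells, but how completely it did so is not known. Pf4 is also made by macrophages. The real split called 6 lists and the highest of the others also 6, in 4 of the 10 splits, which are too few for a share under 0.05. An effect of genotype on the tumours' makeup was not tested.

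A difference that follows abundance stays open for the lower Lyz2, which went from -2.36 to -1.74 (adjusted p = 0.565) once the trend was removed, since its place at percentile 0.251 of the 398 genes averaging above 10, below all others, was also the last before the removal. A candidate explanation is a Cre recombinase inserted at the Lyz2 locus, as in a common macrophage driver line, though the labels name no driver. It stays open, because its test restates the fall that prompted it. The distance of Lyz2 from the median of the tissue-macrophage list was -2.31, against -2.36 for Lyz2 itself, the list's median being -0.05. The 95% interval of -3.39 to -1.23 uses the SE of Lyz2 alone and holds the list's median fixed. The paralog Lyz1, which shares sequence with Lyz2 and was chosen after its values were seen, was at 9.88, 5.05 and 13.08 in PtipWT and 9.23, 10.81 and 11.41 in PtipcKO. Lyz1 lay below Lyz2 in every PtipcKO library (13.01, 13.97 and 11.63 for Lyz2). These values argue against reads counted for Lyz1 as the whole of the fall of Lyz2. Reads that fit both copies and were left uncounted cannot be seen here. A response of Lyz2 to the loss of PTIP stays open and untested.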
